A study of Mus musculus with 56 samples.

How the data were processed

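Total RNA of mouse ovaries and pituitaries was labelled with Cy3 and hybridised by the authors to 1-colour Agilent expression arrays of 1 design, 1 array per sample, 56 arrays in all. Per the file headers, each intensity was read from the scan with Agilent Feature Extraction 10.7.3.1, with the background subtracted, spatial and multiplicative detrending applied and a surrogate intensity given to spots that were not above background; nothing was normalised between arrays. Those processed signals are the deposited intensity values that were used here. The mean spot brightness and the median local background, both deposited as intensity in scanner counts without normalisation, were used for an alternative. The deposited series table holds log2 values that the authors derived from the processed signal. From the values themselves, it is the log2 signal shifted by the 75th percentile of each array and centred per probe on a median over arrays. Its column medians ran from -0.209 to 0.391 in WT ovary, from -0.315 to 0.319 in the genotype ovaries and from -0.943 to 0.444 in pituitary. The pituitary arrays were centred among themselves. Over which set the ovary arrays were centred is not stated and remains unknown, which leaves differences between arrays unaffected.

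The design holds 55681 distinct probes on 59305 spots besides controls, and repeated spots of a probe were averaged. Of these probes 27235 (48.9%) matched a RefSeq transcript of the reference table, and 2838 were given the current symbol where it differed from that in the file. Positions are those of build mm9 in the file headers. The log2 processed signal of each array was shifted by the 75th percentile of that array. In pituitary, where most probes were near background, the percentile was taken over probes well above background on all 13 arrays. A probe was kept when the scanner software called it well above background on at least 3 arrays of the fit. The brightest probe of each gene name then stood for the gene, which left 32224 features in WT ovary, 28203 in the genotype ovaries and 13494 in pituitary. Spots that the software called uneven or far from their repeats were treated as missing, and saturated spots were kept. A fold change against a group with no array above background is given as a bound against the background level.

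The percentage of probes well above background and the net signal of negative controls were read from each file, and the number of arrays limits the precision. Correlations between arrays were checked for copies: the highest were 0.995, 0.993 and 0.991, and 0 pairs exceeded the bound set for a copied file. Slides and scans were read from the files and are numbered here from 1 to 11 and from 1 to 8. Slide 1 held all floxed and Sf1Cre ovary arrays of 90 h and slide 2 those of 78 h but Sf1Cre replicate 1. The null arrays were on slides 6, 8 and 9, and both pituitary slides, 10 and 11, held all 4 groups. The WT arrays were on slides 3 to 7. The titles of WT 90 h replicate 1, WT 82 h replicate 2, WT 66 h replicate 2 and WT 70 h replicate 2 mark a rerun, without saying what was run again; the arrays of 90 and 66 h are among the doubted arrays below.

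Groups follow the labels. Some titles end in a number, and the labels do not say what it marks. In ovaries at 78 h the deviations from the group means of floxed and Sf1Cre arrays with the same number, 2, 3 or 4, correlated across genes at 0.121, 0.177 and 0.473. Only number 4 correlated best with its own, and Sf1Cre number 3 correlated more with another number (0.242). Whether the numbers pair the arrays is therefore open, and they were used as a block in a second fit alone. WT ovary (21 arrays, 7 times), genotype ovary (22 arrays, 6 groups) and pituitary (13 arrays, 4 groups) were fitted apart with group means in limma 3.58.1 under R 4.3.3, with version 1.17.8 of the data.table package and 1.5.0 of statmod. Contrasts had moderated tests and Benjamini-Hochberg adjusted p under 0.05 as the threshold, and a feature past it is described as called. The rhythm fit had a cosine and a sine of 24 h over the 21 WT arrays and a moderated F test. The rhythm score of an array weighted its values of the genes called in that fit by their WT 90 h minus 78 h difference, and was compared by exact two-sided permutation of arrays, or of genotypes within each hour. The fits were tested on simulated data with the spread of each set and known differences, in which 0 to 10 unchanged features were called per comparison. Figures were drawn with matplotlib 3.10.9.

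Comparisons, tests, 21 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were clock E-box targets, clock activators and genes with ROR elements, steroidogenesis, cholesterol synthesis and uptake, luteal function, granulosa cells, theca and interstitial cells, oocyte, ovulatory response, immune cells, oviduct and ciliated epithelium, adipose tissue, endothelium, blood, immediate early genes, heat shock and cold-inducible genes, glucocorticoid-responsive genes, the cell cycle, gonadotropes, other pituitary cell types, and posterior pituitary and hypothalamus. Lists with at least 3 measured members were tested with camera at its preset correlation of 0.01, with adjustment over the lists of a contrast, and again with an estimated correlation and with fry. Named genes are Arntl, Star and the measured members of both clock lists. To these come the 12 highest and 12 lowest called genes with a gene symbol whose groups did not overlap, up to 4 called members of each list by smallest p, the 12 largest called interactions and the 24 largest called amplitudes. The text gives a selection of these. Genes near Nr5a1 and a list of 28 liver transcripts were chosen after the values were seen.

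Alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation of the processed signal, the series table, no filter, probes above background on all arrays, every probe as a feature, an intensity trend with robust spread, slide or scan as a random or fixed block, each array left out in turn, all 43 ovary arrays in 1 fit, WT of the same hour as the control, a block for the number at the end of the title, and other forms of the rhythm model and score. Added after the data were seen were slide as a fixed block, array weights, fits within single slides, the pituitary percentile over all probes, the numbered arrays without a block, and fits without 8 doubted arrays. These 8 were WT 90 h replicate 1, WT 66 h replicate 2 and WT 74 h replicate 1 (low correlation with other WT arrays), null 90 h replicate 1 (dim), Sf1Cre 78 h replicate 1 (another slide than its group), floxed 90 h replicate 1 (markers of other tissues), null 78 h replicate 3 (liver transcripts) and pituitary Sf1Cre 78 h replicate 2 (a file saved again in a spreadsheet). No array was left out otherwise. Ovary and pituitary were not compared, because the tissues were fitted apart.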

Results

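Gene expression was measured on 1-colour Agilent arrays, 1 array per sample, in 43 ovary and 13 pituitary samples of time-mated mice in early pregnancy. Wild-type (WT) C57Bl/6J ovaries were taken at 66, 70, 74, 78, 82, 86 and 90 h post conception, with 3 arrays at each hour. Zeitgeber time (ZT) 0 is lights on, so 66 and 90 h were ZT12 and 78 h was ZT0. Ovaries of 3 genotypes were taken at 78 and 90 h. Floxed controls, which carry the conditional allele of Arntl (Bmal1, an activator of the circadian clock) without Cre, had 4 arrays at each hour. Ovaries called Sf1Cre here carry the same allele with Cre driven by Nr5a1 (Sf1), a gene of steroidogenic cells and of pituitary gonadotropes, and had 4 arrays at each hour. Ovaries of global Arntl nulls had 3 arrays at each hour. Floxed pituitaries had 3 arrays at 78 h and 4 at 90 h, and Sf1Cre pituitaries had 3 at each hour.

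The percentage of probes well above background ran from 43.6 (WT 86 h replicate 3) to 93.6 in WT ovary, from 52.7 to 73.0 in the genotype ovaries and from 19.3 to 33.7 in pituitary. The net signal of the negative control probes was 28.2 to 116.2 in ovary and 958 to 1821 in pituitary, so that fewer genes could be measured there. The number of arrays per group limits the precision of each value. The labels do not say that each array is a separate animal, so the p-values measure only the spread between these samples. Values are log2 intensities relative to the 75th percentile of the array, given as mean ± SD.

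The WT time series was made to find transcripts that oscillate over the day. Arntl peaked near lights on: its mean was 1.21 ± 0.18 at 78 h and -0.29 ± 0.21 at 66 h (n = 3 each), and the fitted 24 h curve had an amplitude of 0.69 log2 units with a peak at ZT21.8 (adjusted p = 0.026). Dbp, a clock-controlled transcription factor, ran almost opposite to it, from 3.16 ± 0.18 at 74 h to 5.57 ± 0.24 at 86 h (n = 3 each), with an amplitude of 1.16 and a peak at ZT7.82 (adjusted p = 4.5e-05). Nr1d1, which encodes the clock repressor REV-ERBα, had an amplitude of 0.86 and a peak at ZT6.97 (adjusted p = 0.0217). Star, which brings cholesterol into the mitochondria for steroid synthesis, stayed between means of 6.49 and 6.91, with an amplitude of 0.11 and no call.

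In all, 12 of 32224 features passed the rhythm test. Besides the 3 clock genes they were Hcrtr1 (an orexin receptor; amplitude 1.81, peak ZT20.2, adjusted p = 0.00596), H2-M5 (1.57, ZT20.1, adjusted p = 0.013), Drc1 (a part of ciliary dynein regulation; 1.22, ZT19.4) and the transcript AK038006 (0.84, ZT20.8). The others were Ces1d (a carboxylesterase; 0.80, ZT17.9), Ptpn22 (a phosphatase of immune cells; 0.66, ZT22.2), Soat2 (which esterifies cholesterol; 0.63, ZT8.15, adjusted p = 0.0472), Camp (an antimicrobial peptide; 0.62, ZT20.9) and Gnb3 (a G protein subunit; 0.49, ZT22.3). Of the 15 clock E-box targets, the genes that ARNTL and its partners activate, 2 passed over all genes and 7 adjusted over the list alone. Members that missed the threshold over all genes included Hlf with an amplitude of 0.45 (adjusted p = 0.0936), Per2 with 0.43, Per3 with 0.41, Nr1d2 with 0.38 and Tef with 0.36. Of the 8 clock activators and genes with ROR elements, Arntl passed over all genes and 4 adjusted over the list alone. Genes of cholesterol synthesis and uptake had 8 of 25 members at an unadjusted p under 0.05, with 0 called over all genes and 1 adjusted over the list alone (Fisher's exact test against all features, adjusted p = 9.2e-05). The heat shock and cold-inducible list had 4 of 10 (1 adjusted over the list alone; adjusted p = 0.00358), the E-box list 7 of 15 (adjusted p = 3.6e-05) and the activators 4 of 8 (adjusted p = 0.00171) by the same test, which treats genes as independent.

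The count of rhythmic features depended on single arrays. It fell to 3 without WT 86 h replicate 1, to 4 without WT 74 h replicate 2 or WT 86 h replicate 2, to 5 without WT 86 h replicate 3, to 7 without WT 78 h replicate 2 and to 2 without WT 74 h replicate 3. The calls of Arntl, Drc1, Gnb3 and Soat2 were lost in 10, 11, 14 and 17 of the 21 fits that each left out 1 array. Only 1 feature (Dbp) passed with slide as a fixed block, which also takes up part of the hours, as slide 4 held 66 to 78 h and slide 5 held 82 to 90 h, and 32 passed when the doubted arrays were left out together. In simulated data with the same spread, 32% of features with an amplitude of 0.5 and 74% of those with an amplitude of 1 passed.

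**Figure D1:**
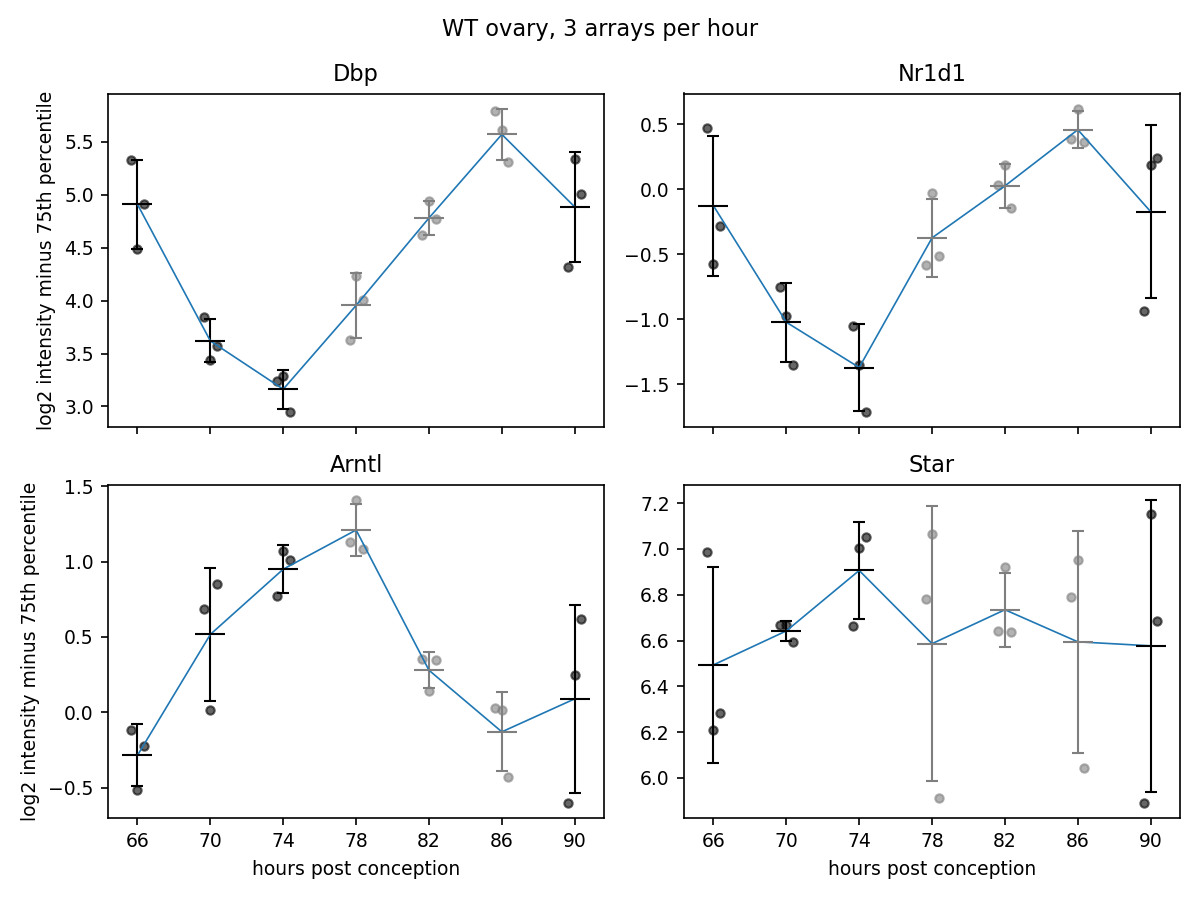
Log2 intensity relative to the 75th percentile of the array (vertical axis) against hours post conception (horizontal axis) in WT ovary, with points for the 3 arrays at each hour, bars for mean and SD, and a line through the means; gray marks 78, 82 and 86 h, in the light, and black the other hours. Dbp means run from 3.16 at 74 h to 5.57 at 86 h and Star means stay between 6.49 and 6.91.

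Between 78 h (ZT0) and 90 h (ZT12), the hours at which the genotypes were compared, WT ovaries had no call in limma (0 of 32224, with 894 at an unadjusted p under 0.05). Arntl had a log2 difference of -1.12 and Star of -0.01, both uncalled. Of the E-box targets 12 of 15 were higher at 90 h (median 0.29; 0 called over all genes, 2 higher adjusted over the list alone), among them Dbp with 0.93, Hlf with 0.70, Per2 with 0.82 and Per3 with 0.92, and Nr1d1 had 0.20. The list's camera test passed with the preset correlation (adjusted p = 1.3e-07) and not with an estimated correlation (adjusted p = 0.162). Of the 8 activators and ROR element genes, 7 were lower at 90 h (median -0.43, 1 lower adjusted over the list alone; Clock had -0.55; camera adjusted p = 0.00495, and adjusted p = 0.11 with an estimated correlation). Oocyte genes (median -0.57, adjusted p = 0.000756), cell cycle genes (-0.38, adjusted p = 0.00216) and heat shock genes (-0.49, adjusted p = 0.00843) had lower medians with the preset correlation, and blood (0.52, adjusted p = 7.4e-05), adipose tissue (0.35, adjusted p = 0.0292) and cholesterol synthesis genes (0.08, adjusted p = 0.000534) higher ones, all with 0 members called. With an estimated correlation the adjusted p-values of these 6 lists were 0.385 to 0.565. The median of all features was itself -0.19. In simulated data 61% of differences of 2 log2 units were called.

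From 66 to 90 h, both ZT12 and 1 day apart, 0 of 32224 features were called in limma (1202 at an unadjusted p under 0.05). Arntl differed by 0.37, Dbp by -0.02 and Star by 0.08. Markers of adipose tissue (median 1.33, camera adjusted p = 6.4e-06) and blood (0.84, adjusted p = 1.2e-09) were higher at 90 h with 0 members called; with an estimated correlation both had an adjusted p = 0.104. Smaller shifts were those of cholesterol synthesis (median 0.21), luteal function (0.14), immune cells (0.10), endothelium (0.09), steroidogenesis (0.04) and the cell cycle (-0.32), whose adjusted p-values with an estimated correlation were 0.32 to 0.774.

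At 78 h the Sf1Cre ovaries were set against the floxed controls to ask what loss of ARNTL in steroidogenic cells changes. The Arntl probe did not separate them (1.03 ± 0.12 against 1.08 ± 0.09, n = 4 each; log2 difference -0.05, not called). This probe (A_55_P2408588, mm9 chromosome 7, 120457261 to 120457320) was the 1 probe of Arntl on the array, and the labels do not name the deleted part of the gene, so its signal checks no deletion. Star fell by 3.18 log2 units (SE 0.53, adjusted p = 0.00945), from 6.33 ± 0.65 to 3.15 ± 0.95 (n = 4 each), and its other probe gave -2.99. Clock genes moved both ways. Nr1d2 fell by 2.23, Per3 by a log2 difference of -1.39 and Dbp by a difference of -1.02 (adjusted p = 0.0452), whereas the repressor Cry1 rose by 1.23 and Npas2, a partner of ARNTL, rose by 2.57 (adjusted p = 0.00076).

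Among the largest differences, Dner (a Notch ligand of neurons) was at least 18.6-fold higher in Sf1Cre ovaries, with no floxed array above background (log2 difference 5.39, adjusted p = 0.000113). Galntl5 rose by 4.19, the adrenergic receptor gene Adra2c by 4.08, the receptor gene Insrr by 2.80 and Nr6a1, an orphan nuclear receptor gene whose probe lies beside Nr5a1, by 2.13. Ms4a10 had a log2 difference of -3.10, the chloride channel gene Clic3 of -2.61 and the transporter gene Slc16a5 of -2.55. The phosphatase gene Dusp1 fell by 1.69. Cyp1b1 rose by 0.58, a call that was lost in 19 of 22 fits that each left out 1 array (0.52 to 0.64) and in 9 of 16 other alternatives. In null against floxed ovaries at 78 h Dner (4.87) was called higher and Ms4a10 (-2.54), Clic3 (-4.72), Slc16a5 (-2.86) and Dusp1 (-2.88) lower. Galntl5 (-0.01), Adra2c (0.72), Insrr (-0.60) and Cyp1b1 (0.20) were not called there. No array carried Cre without the conditional allele, so effects of Cre alone cannot be told apart.

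Of the 15 E-box targets 1 rose and 3 fell (2 and 4 adjusted over the list alone; median -0.13, camera adjusted p = 0.0464, and adjusted p = 0.565 with an estimated correlation). Nr1d1 at -1.20 and Per1 at -0.54 were not called. Of the 8 activators and ROR element genes 1 rose and the list shifted up (3 adjusted over the list alone; median 0.55, adjusted p = 6.5e-07, and adjusted p = 0.000835 with an estimated correlation); Rora was at 0.66 without a call. Genes of cholesterol synthesis and uptake were lower as a list, with 23 of 25 below 0 (median -0.60, 0 called over all genes, 12 lower adjusted over the list alone; camera adjusted p = 9.5e-18, and adjusted p = 0.066 with an estimated correlation). Heat shock genes (median -0.25, 3 lower adjusted over the list alone) and glucocorticoid-responsive genes (-0.19, 1 lower and 1 higher adjusted over the list alone) passed with the preset correlation only, with adjusted p = 0.166 and adjusted p = 0.565 with an estimated correlation. Steroidogenesis had 1 member higher and 1 lower.

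In total 86 of 28203 features were called, 24 higher and 62 lower. Sf1Cre replicate 1 was on slide 9 and the other 7 arrays on slide 2. With slide as a fixed block 43 were called, and 1 within slide 2 alone. The medians of the lists were then -0.65 for cholesterol synthesis, 0.47 for the activators and -0.28 for the E-box targets, under either. The call of Star was lost without floxed 78 h replicate 1 (-2.89) or Sf1Cre 78 h replicate 2 (-2.84) and within slide 2 (-3.24), where those of Npas2 (2.43), Cry1 (1.32) and Dbp (-1.21) were lost too. The calls of Nr1d2 (-1.94) and Per3 (-1.29) were lost with slide or scan as a fixed block, and that of Dbp in 18 of 22 fits that each left out 1 array (-1.21 to -0.89). Nr6a1 was not called without Sf1Cre 78 h replicate 4 (1.93). With the number in the titles as a block, in the 6 arrays that carry one, 0 were called in limma (1625 at an unadjusted p under 0.05), and 0 (1311) in the same arrays without the block. Star was then at -2.95 in both. The camera tests of the cholesterol (adjusted p = 1.4e-09), activator (adjusted p = 3.5e-05) and E-box lists (adjusted p = 0.0227) passed with the block and the preset correlation, and those of the heat shock and glucocorticoid-responsive lists did not (adjusted p = 0.0659 for both). Oocyte (adjusted p = 0.0402), immune cell (adjusted p = 0.0402) and adipose genes (adjusted p = 0.0227) then shifted up, and no list passed with an estimated correlation (adjusted p = 0.806 to 0.968). Leaving out 1 array gave 33 to 123 calls (33 without floxed 78 h replicate 1, 46 without floxed 78 h replicate 2, 56 without Sf1Cre 78 h replicate 1, 39 without replicate 2 and 42 without replicate 4).

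Sf1Cre and floxed ovaries were compared at 90 h in the same way. Arntl was at 0.26 ± 0.28 in Sf1Cre and 0.13 ± 0.25 in floxed ovaries (n = 4 each; adjusted p = 0.916). Dbp fell by 2.15 (SE 0.21, adjusted p = 1.6e-05), from 5.50 ± 0.38 to 3.35 ± 0.24 (n = 4 each), Nr1d1 fell by 2.31 (adjusted p = 0.00033), Nr1d2 by a log2 difference of -2.19 and Per3 by -1.89. Npas2 rose by 3.01 (adjusted p = 1.7e-05), Cry2 by 1.80, Cry1 by 1.08, Nfil3 (a repressor of Dbp target sites) by 1.42 and Rora by 1.52 (its other probe, uncalled, at -0.51). Star fell by 3.17 (SE 0.53, adjusted p = 0.00332), from 7.08 ± 0.26 to 3.91 ± 1.19 (n = 4 each), and its other probe gave -3.61. Per1, at -0.01, was not called.

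Dner again rose, by 5.43, as did Galntl5 by 4.52, Insrr by 4.49, Adra2c by 3.77 and the related receptor gene Adra2a by 3.61. Avpr1a, a vasopressin receptor gene, was at least 11.6-fold higher, with no floxed array above background. Loxl4, a matrix enzyme gene, rose by 3.98, Spp1 (osteopontin) by 3.49 and Cdkn1a, a cell cycle inhibitor, by 2.70. Ms4a10 had a log2 difference of -3.27, Vnn3 of -3.10 and the cadherin gene Cdh15 of -3.04, and Slc16a5 was at least 11.4-fold lower, with no Sf1Cre array above background. The lipase gene Lipe fell by 1.24 and Errfi1 rose by 1.01; their calls were lost in 13 and 19 of 22 fits that each left out 1 array and in 11 and 10 of 16 other alternatives. Of 86 features called at 78 h, 85 had the same sign at 90 h. At both hours 21 were called higher and 36 lower and 0 in opposite directions, where 0.21 and 0.35 would be called at both by chance. In null against floxed ovaries at 90 h Ms4a10 (-3.70), Vnn3 (-4.51), Cdh15 (-4.50) and Slc16a5 (-4.36) were called lower too. Of the rises named here, only that of Cdkn1a (1.56) was called higher there, and Galntl5 had a called difference of -2.13. Dner (1.68), Insrr (0.11), Adra2c (-1.45), Adra2a (-0.62), Avpr1a (2.08), Loxl4 (1.01), Spp1 (1.60) and Errfi1 (0.47) were not called.

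Of the 15 E-box targets 2 rose and 4 fell (the same counts adjusted over the list alone; median -0.26, camera adjusted p = 0.0011, and adjusted p = 0.204 with an estimated correlation). Of the 8 activators and ROR element genes 4 rose and none fell (5 adjusted over the list alone; median 0.74, adjusted p = 1.5e-09, and adjusted p = 0.00012 with an estimated correlation). Of the 25 cholesterol genes 2 fell, Fdps by a log2 difference of -1.51 and Nsdhl by -1.11, both enzymes of sterol synthesis, whose calls were lost in 6 and 13 of 22 fits that each left out 1 array (11 lower adjusted over the list alone; median -0.58, adjusted p = 1.3e-11, and adjusted p = 0.154 with an estimated correlation). The ovulatory response genes (median 0.40, 4 higher adjusted over the list alone) and the immediate early genes (0.68, 5 higher adjusted over the list alone) shifted up with the preset correlation, with adjusted p = 0.0811 and adjusted p = 0.478 with an estimated correlation and 0 members called over all genes. So did immune cell markers (0.23), whereas granulosa (-0.30) and cell cycle genes (-0.23) shifted down, each with 0 members called; with an estimated correlation their adjusted p-values were 0.479, 0.479 and 0.594.

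Of 28203 features 406 were called, 247 higher and 159 lower. All 8 arrays were on slide 1, and 232 features were called within it, with the same list medians of 0.74 for the activators, -0.58 for cholesterol synthesis and -0.26 for the E-box targets. Without floxed 90 h replicate 2 the count was 200, without replicate 3 249, without replicate 4 242, without Sf1Cre 90 h replicate 2 208 and without null 90 h replicate 1, which sets part of the pooled spread, 663. The calls of Dbp, Npas2, Nfil3 and Rora held in all 22 fits that each left out 1 array. Groups did not overlap in 3.81% of features at 78 h and 8.07% at 90 h, where chance gives 2.86%.

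The change of the Sf1Cre difference from 78 to 90 h was tested as an interaction. It gave 0 calls in limma (1466 of 28203 at an unadjusted p under 0.05), with Dbp at -1.13, Nr1d1 at -1.11, Nfil3 at 0.97, Rora at 0.86, Arntl at 0.17 and Star at 0.01. The activators and ROR element genes shifted up as a list (median 0.37, 2 higher adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.139 with an estimated correlation). The 6 other lists that passed did so with the preset correlation only: ovulatory response (median 0.53), immediate early (0.49) and glucocorticoid-responsive genes (0.53) upward, and oocyte (-0.33), granulosa (-0.27) and cell cycle genes (-0.19) downward, with adjusted p-values of 0.356 to 0.531 with an estimated correlation. In simulated data 43% of interactions of 2 log2 units were called.

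Ovaries of the global nulls were compared with the same floxed controls at 78 h. Arntl was at 0.85 ± 0.12 (n = 3) against 1.08 ± 0.09 (n = 4), a log2 difference of -0.23 without a call. Star fell by 4.98 (SE 0.58), to 1.35 ± 0.23 (n = 3), and Hsd17b7, an enzyme of both cholesterol and estradiol synthesis, fell by 3.70. Cyp17a1, which makes androgens in theca cells, rose by 2.29. The clock genes Nr1d2, Per3, Nr1d1 and Dbp had differences of -3.23, -1.70, -1.19 and -0.75, all called, and Npas2, Cry1 and Nfil3 rose by 2.61, 1.18 and 1.01, whereas Clock fell by 0.79. Among the largest falls, Bpifb6 fell by 7.28, Ssu2 by a log2 difference of -5.45 and the peptidase gene Mmel1 by -4.54, and the potassium channel gene Kcnj16 was at least 54.6-fold lower, with no null array above background.

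The largest rises were S100g (a calcium-binding protein; 7.60), the Wnt antagonist Sfrp2 (6.01) and genes abundant in liver: Fabp1 rose by 6.91 and the major urinary protein gene Mup17 by 6.71, and Alb (albumin) and Fgg (fibrinogen) were at least 43.5-fold and at least 17.2-fold higher. Without null 78 h replicate 3, Fabp1 was at 5.55 without a call and Mup17 at 5.44 with one, and the calls of all 4 were lost with slide as a fixed block. The 20 of 28 liver transcripts with low WT signal had medians of -2.92, -1.69 and 0.62 in null 78 h replicates 1 to 3 and of -1.66 in floxed 90 h replicate 3. Sf1Cre 90 h replicate 2 (-2.94) and floxed 90 h replicate 1 (-3.17) were near null 78 h replicate 1, and the other ovary arrays had medians of -7.20 to -3.49, the null 90 h arrays among them with -6.76 to -5.64. Of the 25 cholesterol genes 1 rose and 19 fell (2 and 21 adjusted over the list alone; median -1.40, camera adjusted p = 8.9e-14, and adjusted p = 0.29 with an estimated correlation), with Fdps at -2.74, Sc5d at -2.55 and Idi1 at -2.27. No other list passed camera. Steroidogenesis had 2 higher and 4 lower of 20, Fdx1 (which carries electrons to steroid-making enzymes) among the lower at -0.90, and luteal function 2 higher and 4 lower of 15, among them Cdkn1a at 3.14 and the prolactin receptor gene Prlr at -1.25 and Cdkn1b at -0.95. Theca and interstitial cells had 5 higher and none lower (Col1a1 rose by 2.02), granulosa cells 2 higher (Inhba by 1.31 and Gata4 by 1.21) and the ovulatory response 5 higher (Tnfaip6 by 1.56, Cited4 by 1.54). Of the immediate early genes 5 rose and 1 fell, with Egr2 at 2.26, Fosb at 1.83 and Dusp1 at -2.88.

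Of 28203 features 5536 were called, 3438 higher and 2098 lower. None of the null arrays shared a slide with a floxed array: with slide as a fixed block, where null and floxed arrays are linked through Sf1Cre 78 h replicate 1 alone, 10 features were called (among them Ssu2, Mmel1, Bpifb6 and Kcnj16), Cited4 turned to -0.77, and the median of the cholesterol list was -1.40 with 0 members called. With slide as a random block 2368 were called, and 1295 against WT ovaries of the same hour. Against WT Star had -5.24, Hsd17b7 -3.91, Nr1d2 -3.11, Dbp -1.72 and Npas2 2.06, all called, whereas Cry1 (1.14), Fdx1 (-0.64), Gata4 (0.68), Col1a1 (0.94), Cited4 (0.14), Clock and Prlr were not called. The calls of Dbp and Clock against floxed controls were lost in 5 and 6 of 22 fits that each left out 1 array. Without null 78 h replicate 1, 2 or 3 the counts were 3614, 2371 and 2162, and without floxed 78 h replicate 2 2857.

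The null ovaries were set against the floxed controls at 90 h as well. Arntl rose by 0.83 against the floxed controls (0.97 ± 0.69, n = 3, against 0.13 ± 0.25, n = 4), and Arntl2 by 1.27. Star fell by 6.25, to 0.83 ± 0.93 (n = 3), and Hsd17b7 and the lipoprotein receptor gene Scarb1 had log2 differences of -5.96 and -3.16. Cyp17a1 rose by 1.61. Of the 25 cholesterol genes 23 fell and none rose (24 adjusted over the list alone; median -2.09, camera adjusted p = 7.6e-33, and adjusted p = 0.0117 with an estimated correlation), among them Tm7sf2 at -4.01, Acat2 at -2.40 and Ebp at -2.09. Dbp, Nr1d2, Nr1d1, Per3, Hlf and Tef had called differences of -2.92, -2.87, -2.67, -1.19, -0.74 and -0.62, that of Hlf lost in 16 of 22 fits that each left out 1 array. Npas2 rose by 1.85 and Rora fell by 0.95.

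Of the 15 E-box targets 6 fell and none rose (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.162 with an estimated correlation). Of the 8 activators and ROR element genes 4 rose and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.0441, and adjusted p = 0.143 with an estimated correlation). Steroidogenesis had 2 higher and 7 lower of 20 (2 and 8 adjusted over the list alone; median -0.45, adjusted p = 0.00104). Luteal function had 1 higher and 7 lower of 15 (1 and 8 adjusted over the list alone; median -0.90, adjusted p = 0.00104), with Sfrp4 at -3.05, Prlr at -1.76, Cdkn1b at -0.90 (its other probe at 0.01) and Cdkn1a at 1.56. With an estimated correlation the adjusted p-values were 0.162 and 0.143. Endothelial markers fell in 5 of 9 (7 adjusted over the list alone; median -1.10, adjusted p = 1.2e-05), with Flt1 at -1.93, Esam at -1.43 and Cdh5 at -1.13. Blood markers fell in 6 of 7 (7 adjusted over the list alone; median -2.18, adjusted p = 5.7e-05), with Hba-a1 at -2.18. With an estimated correlation the adjusted p-values were 0.143 and 0.251. Oocyte genes rose in 4 of 15 (5 adjusted over the list alone; median 0.65, adjusted p = 0.000208, and adjusted p = 0.397 with an estimated correlation), among them Zp3 by 1.07, Npm2 by 0.83 and Bmp15 by 0.70. The call of Bmp15 was lost in 19 of 22 fits that each left out 1 array and in 8 of 13 other alternatives, and that of Cdkn1a in 14 of 22 and 5 of 13. Cell cycle genes rose in 2 of 17 (0 adjusted over the list alone; median 0.26, adjusted p = 0.0499, and adjusted p = 0.646 with an estimated correlation).

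Bpifb6 (-7.89), Kcnj16 (-7.67) and Mmel1 (-5.15) were again far lower in null ovaries, and Ssu2 fell by 6.00. Sfrp2 rose by 3.98, the chemokine genes Ccl2 by 3.02 and Ccl7 by 2.69, and Comp (a cartilage matrix protein) by 2.98, and the chemokine gene Cxcl5 was at least 5.84-fold higher, with no floxed array above background. The glucocorticoid-responsive genes Fkbp5 and Sgk1 had differences of -1.75 and -1.62 and Dusp1 of -3.67.

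In total 3755 of 28203 features were called, 1671 higher and 2084 lower, with slide 6 for the null and slide 1 for the floxed arrays, so that no fixed slide term could be fitted. With slide as a random block 1855 were called, with 21 of the cholesterol genes, 5 of the endothelial, 3 of the blood and 2 of the oocyte genes. Against WT of the same hour 2859 were called, with 20 cholesterol, 4 endothelial, 1 blood and 9 oocyte genes in the same directions. Star had -5.74 against WT, Hsd17b7 -4.98, Dbp -2.30, Nr1d1 -2.47, Npas2 2.54, Cyp17a1 2.00 and Arntl 0.88, all called, whereas Tef, Hlf, Arntl2, Cdh5, Cxcl5, Hba-a1 and the oocyte genes Npm2 and Bmp15 were not called, and the median of the steroidogenesis list was 0.06. The calls of Arntl and Cyp17a1 against floxed controls were lost without floxed 90 h replicate 1, 2 or 4 or null 90 h replicate 2 or 3 (0.62 to 0.81 and 1.35 to 1.57). With slide or scan as a random block they were lost too (0.83 and 0.82 for Arntl, 1.61 and 1.59 for Cyp17a1), as were those of Tef, Hlf, Bmp15 and Cdkn1a, and with scan those of Zp3 (1.02) and Npm2 (0.82). Without null 90 h replicate 1, 2 or 3 the counts were 7605, 2234 and 1837, and without the doubted arrays 6972. Groups did not overlap in 42.0% of features at 78 h and 22.6% at 90 h, where chance gives 5.71%.

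The null and Sf1Cre differences share their floxed controls, which makes them correlate by itself. At 78 h 8 features were called higher and 51 lower in both, where 2.90 and 4.63 would be by chance, with 2 in opposite directions; at 90 h these were 61 and 105, where 14.7 and 11.8 would be, and 18. The correlation across genes, which are not independent replicates, was 0.474 at 78 h and 0.393 at 90 h, against 0.461 and 0.464 in simulated data with shared controls and no other link, and the covariance was 0.173 and 0.147 against 0.0789 and 0.0792. With WT controls for the null arrays, which shares no array, the correlation was 0.242 at 78 h and 0.0288 at 90 h. Called in both were then 7 higher and 58 lower at 78 h, where 0.63 and 1.97 would be by chance, and 52 and 98 at 90 h, where 16.4 and 5.64 would be, with 4 and 19 in opposite directions. Of the Sf1Cre calls in that fit 82.8% and 72.4% had the same sign in null against WT ovaries. The direct difference of Sf1Cre and null ovaries had 2114 calls at 78 h and 4224 at 90 h.

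The change of the null difference from 78 to 90 h included clock genes. Arntl and Arntl2 fell from 78 to 90 h in floxed and not in null ovaries, with interactions of 1.06 (adjusted p = 0.0483) and 1.12, and the interactions of Dbp (-2.16, adjusted p = 0.0023) and Nr1d1 (-1.48, adjusted p = 0.0479) were negative. The calls of Arntl and Nr1d1 were lost in 18 and 17 of 22 fits that each left out 1 array (0.85 to 1.46 and -1.73 to -1.13) and in 6 and 5 of 12 other alternatives. Arntl2 was not called without null 90 h replicate 3 (0.92). Star, at -1.26, was not called. Of the 25 cholesterol genes 8 had a called negative interaction and none a positive one (14 adjusted over the list alone; median -0.98), among them Hsd17b7 at -2.26 (another of its probes, uncalled, at -0.10), Tm7sf2 at -2.04 and Acat2 at -1.45; Scarb1 was at -2.18 and the endothelial receptor gene Flt1 at -1.78 (another of its probes at 0.82 without a call). The list's camera test gave adjusted p = 5.4e-06, and adjusted p = 0.458 with an estimated correlation. Lists with fewer calls also passed with the preset correlation only: E-box targets, steroidogenesis, luteal function, endothelium, blood and other pituitary cell types downward (adjusted p = 0.458 to 0.501 with an estimated correlation) and oocyte and cell cycle genes upward (adjusted p = 0.501 for both).

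Of 28203 features 2836 had a called interaction, 1319 positive and 1517 negative. With slide as a random block 468 were called, with scan as a random block 1306 and without the doubted arrays 4693. The calls of Arntl (1.08), Arntl2 (1.09), Nr1d1 (-1.37), Hsd17b7 (-2.21), Tm7sf2 (-2.02), Scarb1 (-2.04) and Flt1 (-1.68) were lost with slide as a random block, and those of Dbp and Acat2 were kept.

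**Figure D2:**
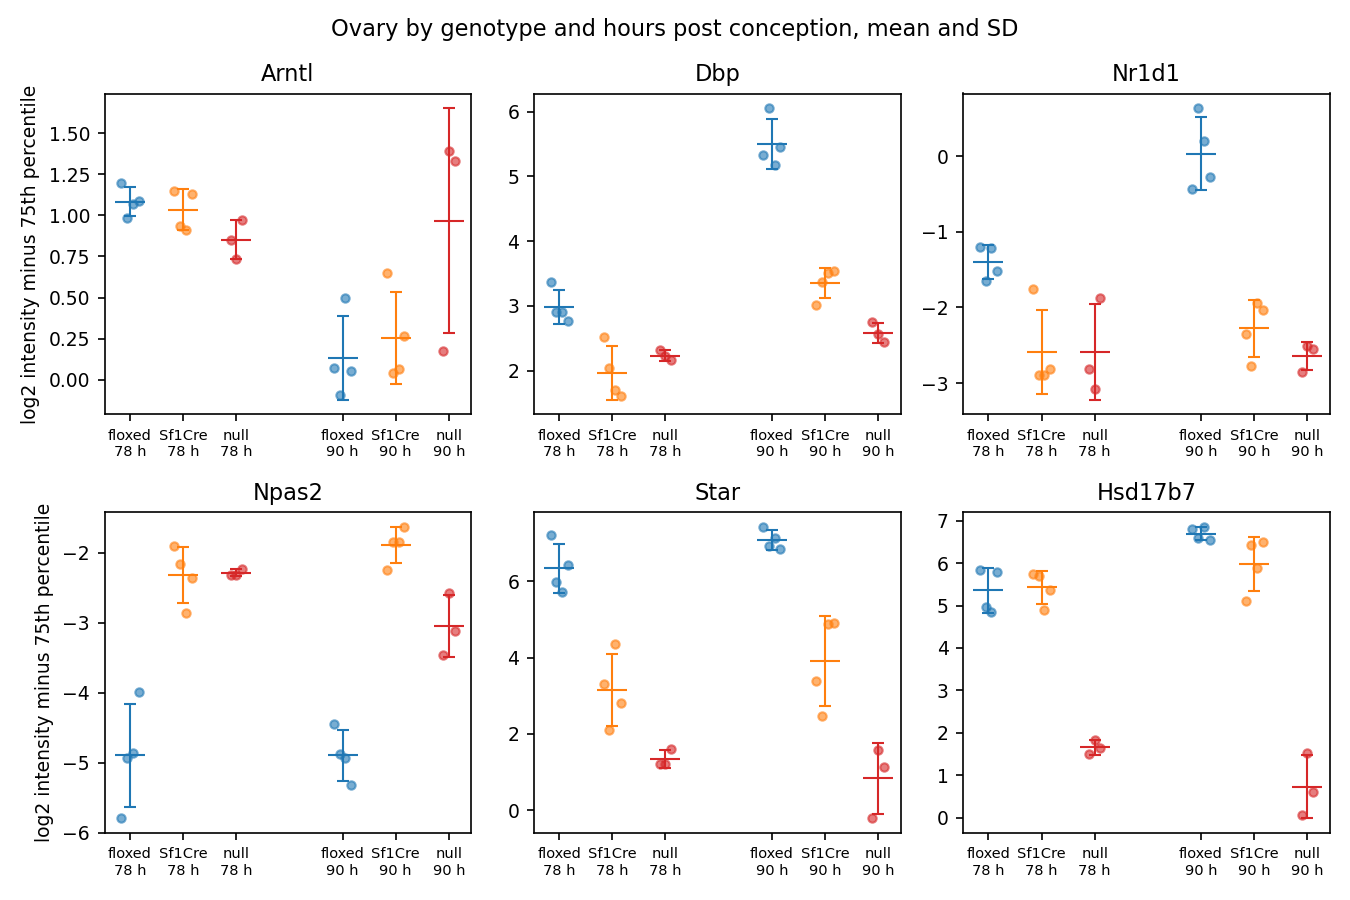
Log2 intensity relative to the 75th percentile of the array (vertical axes) for 6 genes in floxed, Sf1Cre and null ovaries at 78 and 90 h (horizontal axes), with a point per array and bars for mean and SD. Star means are 6.33 and 7.08 in floxed, 3.15 and 3.91 in Sf1Cre and 1.35 and 0.83 in null ovaries, and Arntl overlaps between floxed and Sf1Cre ovaries at both hours.

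Within each genotype, 90 h (ZT12) was compared with 78 h (ZT0). In floxed ovaries Arntl fell by 0.95 (adjusted p = 0.0031) and the E-box targets Dbp, Nr1d1, Usp2, Hlf, Tef, Per1 and Cry1 rose by 2.52, 1.43, 1.18, 1.11, 1.06, 0.87 and 0.65. The call of Per1 was lost in 3 of 12 alternatives and 2 of 22 fits that each left out 1 array, and that of Cry1 in 3 and 5. Star was at 0.75 without a call. In Sf1Cre ovaries Arntl fell by 0.78 and Per1, Dbp, Usp2, Tef and Hlf rose by 1.40 (its other probe, uncalled, at -0.23), 1.39, 1.03, 0.86 and 0.62, whereas Nr1d1, at 0.32, and Star, at 0.76, were not called. The call of Hlf there was lost in 15 of 22 fits that each left out 1 array and with slide as a random block (0.59). In null ovaries Dbp (0.35), Nr1d1 (-0.05), Arntl (0.11) and Star (-0.51) were not called and Rora fell by 0.83.

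In floxed ovaries 7 of 15 E-box targets rose and none fell (camera adjusted p = 0.000503, and adjusted p = 0.255 with an estimated correlation), as did 16 of 25 cholesterol genes (adjusted p = 5.1e-06, and adjusted p = 0.343 with an estimated correlation), the same counts as adjusted over the list alone. Among them Tm7sf2 rose by 1.83, the sterol regulator Srebf2 by 1.46 and Hsd17b7 by 1.34 (another of its probes, uncalled, at 0.11). Steroidogenesis had 5 higher of 20, with Scarb1 at 1.90 and Hsd17b1 at 1.35 (5 adjusted over the list alone; adjusted p = 0.0182, and adjusted p = 0.343 with an estimated correlation). Of 15 granulosa genes 7 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000669, and adjusted p = 0.255 with an estimated correlation), with Amh at 2.32 and the activin inhibitor Fst at 2.13. Nog, which inhibits BMP signals, rose by 3.76 in floxed and 3.51 in Sf1Cre ovaries. Ltb4r2, a leukotriene receptor gene, was at least 5.74-fold higher, and Dsg1c and Dnajb8 were at least 8.86-fold and at least 10.3-fold lower. Flt1 rose by 1.49, although 1 of its 3 probes was called in the opposite direction (-1.39), and the glucocorticoid-responsive gene Fkbp5 rose by 1.41.

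In Sf1Cre ovaries 7 of 15 E-box targets rose (7 adjusted over the list alone; adjusted p = 0.00514), as did 15 of 25 cholesterol genes (18 adjusted over the list alone; adjusted p = 4.2e-06), 8 of 12 immediate early genes (8 adjusted over the list alone; adjusted p = 0.000807) and 8 of 12 glucocorticoid-responsive genes (8 adjusted over the list alone; adjusted p = 0.00105), with none lower. So did 7 of 15 luteal genes (9 adjusted over the list alone; adjusted p = 0.0111), 5 of 10 heat shock genes (5 adjusted over the list alone; adjusted p = 0.00738) and 4 of 11 gonadotrope genes (4 adjusted over the list alone; adjusted p = 0.0204), with none lower. Of 20 steroidogenesis genes 7 rose and 1 fell (adjusted p = 0.00514) and of 15 granulosa genes 4 rose and 1 fell (adjusted p = 0.0234), with 7 and 1 and 5 and 1 adjusted over the list alone. With an estimated correlation the adjusted p-values of these 9 lists were 0.247 to 0.353. In null ovaries 4 of 15 oocyte genes rose (11 adjusted over the list alone; adjusted p = 3.8e-06), among them Zp1 by 1.38, Zp3 by 1.08 and Npm2 by 1.02, and 3 of 17 cell cycle genes (11 adjusted over the list alone; adjusted p = 5.8e-06). Of 15 granulosa genes 1 rose (2 adjusted over the list alone; adjusted p = 0.0355) and 1 of 7 blood genes fell (6 adjusted over the list alone; adjusted p = 0.00257). With an estimated correlation the adjusted p was 0.48 for these 4 lists. Acat2 (-0.86) and Tspo (-0.72) fell and Stard3 rose by 0.60. The calls of Zp1, Zp3, Acat2, Tspo, Stard3 and Rora in null ovaries were each lost with slide or scan as a random block, without the doubted arrays and in 4 to 6 of 22 fits that left out 1 array.

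The counts were 8507 in floxed (4572 higher), 7974 in Sf1Cre (4545 higher) and 1966 in null ovaries (793 higher, 1173 lower). No slide held both hours of any of these genotypes, so hour and slide cannot be told apart within a genotype. Floxed and Sf1Cre arrays of 90 h were on the same slide, slide 1, and their differences correlated across genes at 0.734, which counts genes as if independent; that of WT ovaries over the same hours, on other slides, correlated with the floxed difference at 0.0761, and at 0.277 without the doubted arrays, where it had the same sign in 69.7% of the floxed calls against 50% with them. The floxed count was 5464 and the null count 606 with slide as a random block. The null count was 861 without null 78 h replicate 1, 568 without replicate 2, 613 without replicate 3 and 896 without null 90 h replicate 2. Groups did not overlap in 34.7% of features in floxed and 25.7% in Sf1Cre (chance 2.86%) and 33.7% in null ovaries (chance 10%).

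A rhythm score, fixed on the 12 genes called in WT and scaled so that a difference equal to that of WT scores 1, summarised these hours in 1 value per array. In floxed ovaries it was -0.66 ± 0.26 at 78 h and 0.31 ± 0.29 at 90 h (n = 4 each), a difference of 0.967 (exact two-sided permutation p = 0.0286, the smallest that 70 permutations can give). In Sf1Cre ovaries it was -0.32 ± 0.25 and 0.02 ± 0.22 (n = 4 each; difference 0.341, exact permutation p = 0.114), and in null ovaries 0.33 ± 0.30 and 0.54 ± 0.41 (n = 3 each; 0.201, exact permutation p = 0.6, where the smallest possible is 0.1). The Sf1Cre time difference less the floxed had a value of -0.626 (exact permutation of genotypes within each hour, p = 0.0273 of 4900), and the null less the floxed one of -0.766 (p = 0.136 by exact permutation of 1225). Over the 5 permutation tests the Benjamini-Hochberg adjusted p was 0.0714 for the floxed and Sf1Cre against floxed differences. It was 0.17 to 0.6 for the others, so none passed 0.05. With the clock lists left out the Sf1Cre difference was -0.616 (exact permutation p = 0.0673) and with normexp values -0.364 (exact permutation p = 0.173), and without null 90 h replicate 1 the null difference was -0.999 (exact permutation p = 0.0305).

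**Figure D3:**
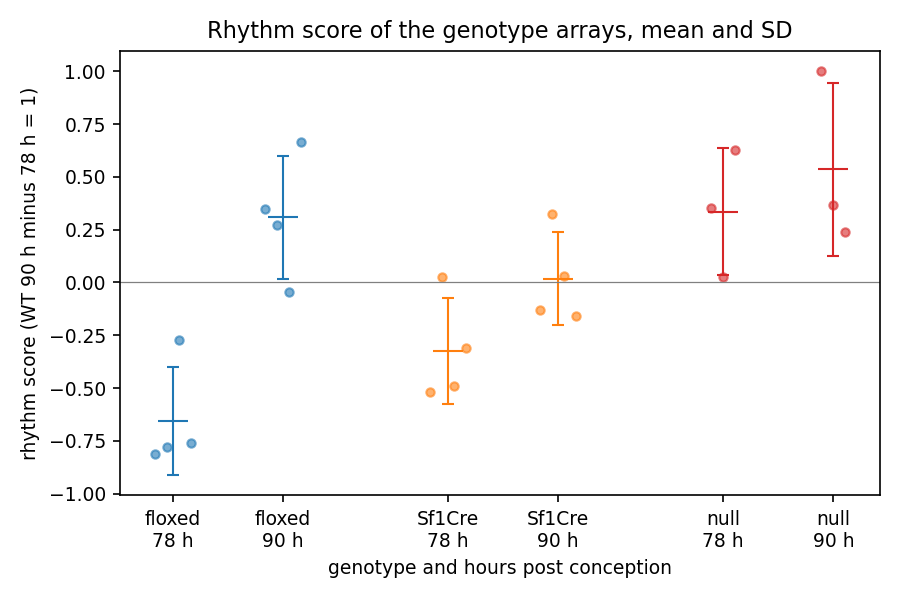
Rhythm score (vertical axis, where the WT 90 h minus 78 h difference equals 1) of each array of floxed, Sf1Cre and null ovaries at 78 and 90 h (horizontal axis), with bars for mean and SD. Floxed means are -0.66 and 0.31, Sf1Cre means -0.32 and 0.02 and null means 0.33 and 0.54.

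In pituitary, Sf1Cre removes Arntl only where Nr5a1 is active, in gonadotropes, and the genotypes were compared in whole glands. Arntl was at -3.36 ± 0.40 in Sf1Cre and -3.04 ± 0.08 in floxed glands at 78 h (n = 3 each) and at -4.82 ± 0.34 (n = 3) and -5.32 ± 0.37 (n = 4) at 90 h. Its probe was above background on 2 of 3 Sf1Cre and 3 of 3 floxed arrays at 78 h, and on 1 of 3 and 1 of 4 at 90 h, so its values at 90 h rest mostly on signal near background. No feature of 13494 was called in limma at 78 h (0, with 312 at an unadjusted p under 0.05), at 90 h (0, with 346) or as an interaction (0, with 433). The differences at 78 and 90 h were -0.32 and 0.50 for Arntl, 0.01 and -0.09 for Dbp, -0.55 and -0.14 for Per1, -0.33 and -0.33 for Nr1d2 and -0.05 and -0.00 for Tef, and the interaction of Arntl was 0.82 and that of Dbp -0.10. The immediate early genes were lower in Sf1Cre glands at 78 h as a list (median -1.25, 0 of 7 called over all genes and 0 adjusted over the list alone; camera adjusted p = 0.00057, and adjusted p = 0.321 with an estimated correlation). In simulated data 68% of differences of 2 log2 units were called at 78 h, 71% at 90 h and 41% of such interactions.

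Time of day changed clock genes in pituitary. In floxed glands Dbp rose by 2.90 from 78 to 90 h (from -1.64 to 1.26; adjusted p = 0.00064), Tef by 1.59 (adjusted p = 0.0244) and Arntl, near background on most arrays at 90 h, fell by 2.28 (adjusted p = 0.0104). In Sf1Cre glands Dbp rose by 2.81 (adjusted p = 0.00191) and Tef by 1.64 (adjusted p = 0.0265). The kinase gene Pim3 was at least 1.94-fold and the lipoxygenase gene Alox12e at least 3.94-fold higher there, with no Sf1Cre array above background at 78 h, and Arntl was at -1.46 without a call. Per1 (1.56 and 1.97), Nr1d2 (1.65 and 1.64) and Usp2 (1.55 and 2.19) were higher at 90 h in floxed and Sf1Cre glands without a call. Of the 9 measured E-box targets 2 rose in each (7 and 6 adjusted over the list alone; medians 1.55 and 1.64, camera adjusted p = 8.1e-12 and 4.5e-07), with an adjusted p = 0.0506 and an adjusted p = 0.221 with an estimated correlation. In floxed glands glucocorticoid-responsive genes (5 higher and 1 lower adjusted over the list alone), gonadotrope genes (0), immediate early genes (4 higher) and steroidogenesis (2 higher) shifted up and the activators (1 lower) and blood genes (0) down with the preset correlation, with adjusted p-values of 0.115 to 0.572 with an estimated correlation. In Sf1Cre glands immediate early genes shifted up (3 higher adjusted over the list alone, 0 over all genes; adjusted p = 0.00985, and adjusted p = 0.651 with an estimated correlation).

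Those 3 calls in floxed and 4 in Sf1Cre glands were all that passed (1408 and 2713 at an unadjusted p under 0.05). Both slides held all 4 groups with 1 or 2 arrays each, which is too few for a count of calls within a slide. Within slides 10 and 11 the E-box medians were 1.40 and 1.76 in floxed and 1.70 and 1.64 in Sf1Cre glands. Leaving out 1 array gave 1 to 10 calls in floxed and 1 to 28 in Sf1Cre glands. In the 13 such fits the call of Tef was lost in 9 in floxed and 10 in Sf1Cre glands, that of Arntl in 4 in floxed glands and those of Alox12e and Pim3 in 7 and 3 in Sf1Cre glands, whereas that of Dbp held in all. Groups did not overlap in 12.4% (chance 5.71%) and 22.1% (chance 10%) of features.

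**Figure D4:**
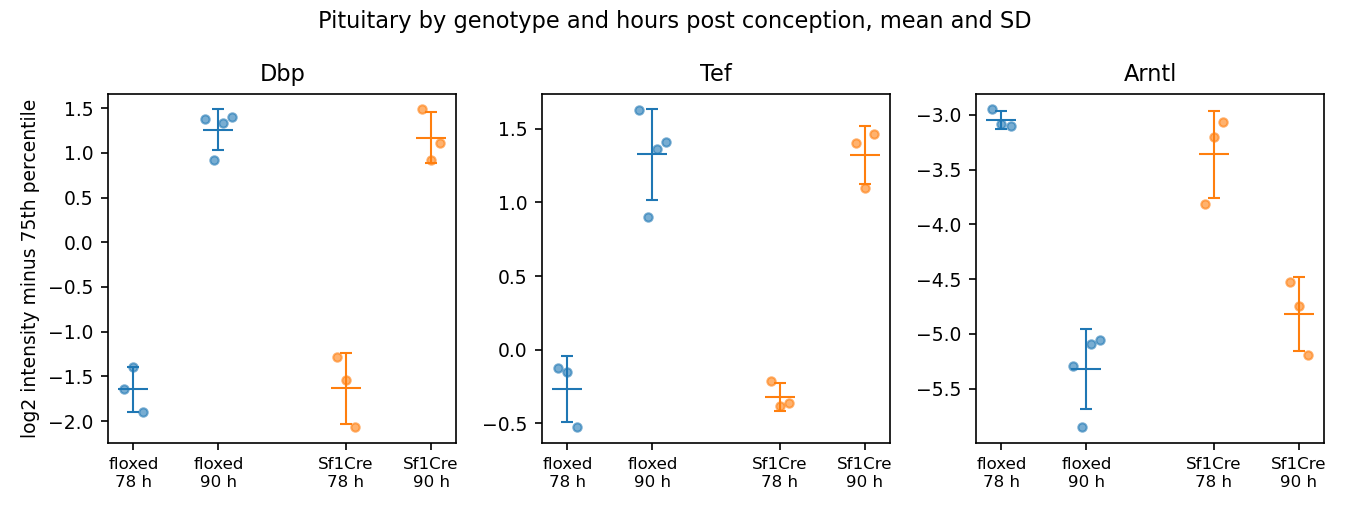
Log2 intensity relative to the 75th percentile of the array, taken over probes above background on all pituitary arrays (vertical axes), for Dbp, Tef and Arntl in floxed and Sf1Cre pituitaries at 78 and 90 h (horizontal axes), with a point per array and bars for mean and SD. Dbp means rise from -1.64 to 1.26 in floxed and from -1.63 to 1.17 in Sf1Cre glands.

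The probes of the main genes lay in build mm9 as the files give them. Star was read by A_52_P165654 on chromosome 8 (26925460 to 26925519), Dbp by A_55_P2032079 on chromosome 7 (52965461 to 52965520), Nr1d1 by A_51_P223776 on chromosome 11 (98630526 to 98631028) and Nr1d2 by A_55_P2148534 on chromosome 14 (19036568 to 19036627). Npas2 was read by A_52_P534749 on chromosome 1 (39418941 to 39419000), Per3 by A_51_P258493 on chromosome 4 (150379256 to 150379315) and Cry1 by A_52_P420500 on chromosome 10 (84594731 to 84594790). Nr6a1 was read by A_55_P2003438 and Nr5a1 by A_55_P2076560, both on chromosome 2 (38582439 to 38582498 and 38548180 to 38548239), Hsd17b7 by A_55_P1997936 on chromosome 1 (171883182 to 171883241) and Dner by A_52_P671132 on chromosome 1 (84366416 to 84366475). Of the named genes with several probes, the 2 probes of Dbp, Star and Nr1d2 and the 3 of Hsd17b7 had the same sign in the comparisons in which they were named. Probes of 1 gene were called in opposite directions for 2 named genes each in the floxed and Sf1Cre comparisons of 90 and 78 h and for 0 in the other comparisons.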

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

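The tests of slides, of liver transcripts and of the region around Nr5a1 were chosen only after the results were seen.

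The change of the null difference from 78 to 90 h passed the interaction test for the clock genes Dbp (-2.16), Nr1d1 (-1.48), Arntl (1.06) and Arntl2 (1.12). The calls of Nr1d1 and Arntl were lost in 17 and 18 of 22 fits that each left out 1 array. The test also passed for the cholesterol genes Hsd17b7 (-2.26, another of its probes at -0.10), Tm7sf2 (-2.04) and Acat2 (-1.45), for Scarb1 (-2.18) and for Flt1 (-1.78). Of these only the calls of Dbp and Acat2 held with slide as a random block, which cannot separate hour from slide in the subtracted floxed change. The rhythm score difference of 90 and 78 h had a value of -0.626 in Sf1Cre against floxed ovaries, which did not pass after adjustment (exact permutation p = 0.0273, adjusted p = 0.0714). It was -0.364 with normexp values (exact permutation p = 0.173) and -0.679 with the clock lists alone (exact permutation p = 0.219).

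A value far from the other 3 arrays of its group was found in 17 of 416 tests of 104 genes, where chance flags about 1 in 20 groups, or 20.8 tests. Floxed 90 h replicate 1 held 4 of them: Dnajb8 at -5.04 against a mean of -6.61 in the others, Hlf at -0.99 against -0.24, Loxl4 at -7.08 against -5.07 and Tm7sf2 at 6.31 against 5.63. Sf1Cre 78 h replicate 1 held 3: Amh at 0.40 against -2.33, Nr1d1 at -1.76 against -2.87 and Nr1d2 at -1.33 against -0.20. Pituitary floxed 90 h replicate 1 held 3: Dbp at 0.92 against 1.37, Pim3 at -4.79 against -3.67 and Alox12e at -2.66 against -2.33. In Sf1Cre 90 h replicate 1, Ebp was at 5.10 against 5.66. Single values stood apart for Fgg in floxed 78 h replicate 4 (-6.64 against -7.95), Amh in floxed 90 h replicate 3 (0.35 against -0.01) and Esam in floxed 90 h replicate 4 (2.77 against 2.40). The same held for Cdkn1b in Sf1Cre 78 h replicate 2 (4.31 against 3.91), Vnn3 in Sf1Cre 78 h replicate 4 (-3.02 against -4.29) and Inhba in Sf1Cre 90 h replicate 4 (5.97 against 5.02). The rhythm score of floxed 78 h replicate 3, at -0.27, lay apart from the others by 0.908 of the range of its group.

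Between 90 and 78 h 8507 features differed in floxed and 7974 in Sf1Cre ovaries, whose 90 h arrays were all on slide 1. The covariance of the WT and floxed differences was 0.0753 of that of Sf1Cre and floxed, and 0.243 without the doubted arrays. WT arrays of 78 and 90 h shared no slide either, so time of day stays open. The floxed and Sf1Cre differences correlated across genes, which are not independent replicates, at 0.734, so that slide 1 standing apart from the other slides is a candidate cause. A difference of the floxed line from WT that appears at 90 h cannot be told apart from it, since 7993 features were called between floxed and WT ovaries at 90 h and 45 at 78 h, and no floxed 90 h array was on another slide.

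Liver transcripts were high in null ovaries at 78 h. Of the 20 listed liver transcripts that were low in WT ovary, 19 were over 1 log2 unit higher in null than in floxed ovaries (median 4.57), and the 8 that WT ovary also expressed had a median difference of 0.50. Across these genes the profile of null 78 h replicate 3 correlated at 0.935 with that of floxed 90 h replicate 3, so liver RNA in these samples is a candidate source. These transcripts were raised outside the null group too: their medians were -2.94 in Sf1Cre 90 h replicate 2 and -3.17 in floxed 90 h replicate 1, against -2.92 in null 78 h replicate 1. Liver transcripts made by null ovaries at both hours are argued against by the null 90 h arrays, whose median difference from floxed ovaries at 78 h was 0.0075. Expression of these genes by null ovaries at 78 h alone stays open, as it was not tested.

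Nr6a1, which lies beside Nr5a1, was higher in Sf1Cre ovaries by 2.13 at 78 h and 2.11 at 90 h, and its difference in null ovaries at 78 h was -0.49. Extra copies of part of the Nr5a1 region carried with the Cre transgene could raise it. Nr5a1 itself had a difference of 0.567 (SE 0.22) at 78 h and 0.498 at 90 h in Sf1Cre ovaries and of 1.25 and 0.67 in Sf1Cre pituitary, all without a call. In null ovaries at 78 h, which lack the transgene, it was called at 1.00 (adjusted p = 0.00864). In Sf1Cre ovaries the 9 other measured genes within 500 kb had differences of -0.74 to 0.40 over both hours, none of them called. Whether copies were carried stays open, as no value decides it. An effect of the loss of ARNTL that null ovaries share is argued against, since Nr6a1 was higher in Sf1Cre than in null ovaries by 2.61 at 78 h (adjusted p = 0.000882) and 2.07 at 90 h, and null and floxed ovaries differed by 0.03 at 90 h.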

How the results depend on the processing

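Slide as a fixed block, array weights, leaving out the doubted arrays, fits within single slides, the pituitary percentile over all probes and the numbered arrays without a block were chosen after seeing the data, and the other alternatives before. Of 3494 named gene values under alternatives, 3016 kept their side of the threshold, 452 lost and 24 gained a call, and 2 reversed: Cited4 in null against floxed ovaries at 78 h was -0.77 with scan or slide as a fixed block. With 1 array left out, 4890 of 5281 kept theirs, 386 lost and 5 gained a call. Sign changes of uncalled genes were not counted. The counts of the pituitary genotype comparisons were 0 in limma under every alternative run (312, 346 and 433 at an unadjusted p under 0.05 in the fits of the report). Scan could not be a block in pituitary, which had 1 scan, no fixed slide term could be fitted to the 90 h minus 78 h differences of the genotypes, and neither fixed term to null at 90 h. Except where fewer arrays or more features were tested, the cause was not tested. Signal over background limits pituitary most, where 19.3 to 33.7% of probes were well above background.

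With scan as a fixed block 1 feature was called between WT 90 and 66 h, 43 between Sf1Cre and floxed ovaries at 78 h and 10 between null and floxed ovaries at 78 h. These last counts were also 43 and 10 with slide as a fixed block, and 1 feature was rhythmic. With slide as a random block the null differences had 2368 calls at 78 h, 1855 at 90 h and 468 as an interaction, the floxed 90 h minus 78 h difference 5464 and the null 606. With scan as a random block the null differences had 1657 at 90 h and 1306 as an interaction, and the null 90 h minus 78 h difference 311. Array weights gave 3 calls between WT 90 and 78 h, 2 between WT 90 and 66 h and 58 rhythmic features. They gave 159 and 799 for Sf1Cre at 78 and 90 h and 2 for its interaction, and 12749, 14089 and 11850 for null at 78 h, at 90 h and as an interaction. They gave 13625 for null 90 h minus 78 h, and in pituitary 3709 for floxed and 11 for Sf1Cre 90 h minus 78 h. Without the doubted arrays 32 features were rhythmic, and null had 6972 calls at 90 h and 4693 as an interaction. The Sf1Cre interaction had 1 call with normexp and quantile normalisation, 1 with probes above background on all arrays, 1 with an intensity trend and robust spread and 2 with all 43 ovary arrays, which gave 727 for null 90 h minus 78 h. With every probe as a feature the 90 h minus 78 h counts were 13115 in floxed and 12000 in Sf1Cre ovaries and 5 in floxed pituitary. With WT controls null at 78 h had 1295. Rhythmic features were 4 with a linear trend, 2 with 7 times as groups, 5 without 66 h and 0 in limma within slide 3, slide 4 and slide 5 (1042, 695 and 1702 at an unadjusted p under 0.05), whose 6, 6 and 5 arrays are too few for this fit to tell. Within slide 1 Sf1Cre had 232 calls at 90 h, and within slide 2 1 at 78 h.

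In pituitary the floxed 90 h minus 78 h count was 1 with normexp and quantile normalisation, with quantile normalisation of the processed signal, with the series table, without a filter and with the percentile of all probes. The Sf1Cre count was then 1, 2, 0, 2 and 0, with 1801 and 1810 at an unadjusted p under 0.05 beside the counts of 0 in limma. Within slides 10 and 11, with 1 or 2 arrays per group and so little power, both were 0 in limma (238 and 2356 in floxed and 2620 and 1814 in Sf1Cre at an unadjusted p under 0.05). The replicate block left Sf1Cre 0 calls in limma at 78 h (1625 at an unadjusted p under 0.05) and 3 at 90 h, and the same arrays without a block 0 (1311) and 99. Arrays with the same number correlated across genes at -0.108, -0.00391 and 0.161 in ovary at 90 h and at -0.251 and -0.0553 in pituitary. Only number 4 in ovary (0.161) correlated best with its own there, so pairing by number was not shown. Fewer arrays, 6 of 8, were in the fits at 78 h. Of 331 list tests 82 passed camera with the preset correlation, 3 with an estimated correlation and 65 fry, 45 of them shared.

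The Sf1Cre 90 h minus 78 h rhythm score was 1.03 with the clock lists alone (-0.679 less the floxed) and 0.489 with sign weights. Scaling moved the median of all features from -0.19 to -0.05 in WT 90 h minus 78 h and from -0.14 to 0.01 in WT 90 h minus 66 h with normexp. With the percentile of all probes it moved in pituitary from 0.10 to -0.25 in Sf1Cre 90 h minus 78 h, from 0.02 to 0.17 in floxed, from 0.03 to -0.36 in the 90 h difference and from 0.08 to -0.42 in the interaction.

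Leaving out 1 array gave 0 to 1 calls between WT 90 and 66 h and 2 to 17 rhythmic features. Sf1Cre had 33 to 123 calls at 78 h, 200 to 663 at 90 h and 0 to 1 as an interaction, and null 2162 to 7859, 1837 to 7605 and 1308 to 5419. The 90 h minus 78 h counts were 6661 to 9779 in floxed, 5430 to 9685 in Sf1Cre and 568 to 2465 in null ovaries, and 1 to 10 and 1 to 28 in floxed and Sf1Cre pituitary. Apart from the Sf1Cre interaction, the highest counts of the genotype ovaries came without null 90 h replicate 1 and those of pituitary without floxed 90 h replicate 1. The lowest were without floxed 78 h replicate 1 and floxed 90 h replicate 2 for Sf1Cre and without null 78 h replicate 3, null 90 h replicate 3 and null 78 h replicate 2 for null. The scores ran from 0.848 to 1.09 in floxed and 0.239 to 0.457 in Sf1Cre ovaries (0.848 without floxed 90 h replicate 4 and 0.457 without Sf1Cre 78 h replicate 2), from -0.753 to -0.508 for their difference and from -0.999 to -0.616 for null against floxed.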

Other observations

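The tests of genes and lists in this part were fixed before their results were seen, whereas the terms of the tests by splits of the arrays were written down only after theirs were seen. In Sf1Cre ovaries 2 genes that respond to cytokine and prolactin receptors were higher at 90 than at 78 h, though no list of such genes was tested: Cish rose by 2.55 (SE 0.43, adjusted p = 0.000464) and Socs1 by 2.61 (SE 0.47, adjusted p = 0.000646), both above background in all 8 arrays. Akr1c18, which inactivates progesterone, rose by 3.32 (adjusted p = 0.0285), a call that was lost without Sf1Cre 78 h replicate 3 (2.32) or Sf1Cre 90 h replicate 2 (3.08) or replicate 4 (3.02), and with slide as a random block (3.33) or scan as a fixed block (3.35). Hour and slide cannot be told apart here. Against floxed ovaries, the interaction had 0 calls in limma (1466 at an unadjusted p under 0.05).

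Some named neural and secretory genes differed in null or Sf1Cre ovaries, in both directions. Pmch (pro-melanin-concentrating hormone) was at least 9.58-fold lower in null than floxed ovaries at 78 h, with no null array above background, and was at -4.74 at 90 h. The vesicle gene Rab27a (-4.80) and the transporter gene Slc12a8 (-4.93) were lower in null ovaries at 90 h, with 2 probes of Slc12a8 called. The glial genes S100b and Mbp had differences of -1.59 and -1.55 there, and S100b one of -1.43 in Sf1Cre ovaries, a call lost without floxed 90 h replicate 1 or 4 or Sf1Cre 90 h replicate 1 or 2 (-1.39 to -1.20). The homeobox gene Rax rose by 4.43 in null ovaries at 78 h. Against WT ovaries of the same hour Rax (2.90) and S100b (-1.04) were not called in null ovaries. In Sf1Cre ovaries at 90 h Fer1l4 rose by 4.32 and the mucin gene Muc5b was at -3.07, uncalled in null ovaries (-2.19 and -0.38). The list of posterior pituitary and hypothalamus, with 8 measured members in the genotype ovaries, had 1 lower in Sf1Cre ovaries at 90 h (1 adjusted over the list alone), 1 higher in null ovaries at 78 h (2 adjusted over the list alone) and 1 higher and 2 lower at 90 h (the same adjusted over the list alone). Markers of oviduct and ciliated epithelium had 2 higher and 1 lower of 12 in null ovaries at 78 h and 1 lower at 90 h (the same adjusted over the list alone), and in WT and Sf1Cre ovaries none was called over all genes (1 higher adjusted over the list alone in Sf1Cre ovaries at 90 h). Neither list passed camera in any comparison.

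The arrays of each comparison were also split in other ways into groups of the same sizes. For Sf1Cre against floxed ovaries at 90 h the real split alone gave as many calls, a share under 0.05 (1 of 35 splits, 406 calls, highest other 8). So it did for null against floxed ovaries at 78 h (1 of 35, 5536 and 2957) and at 90 h (1 of 35, 3755 and 2130). The same holds for 90 h minus 78 h in floxed (8507 and 2) and Sf1Cre ovaries (7974 and 3500), with 1 of 35 splits each. It also holds for the null interaction (2836 and 1154) and the WT rhythm (12 and 1), with 1 of 100 drawn splits each. In the null comparisons and in 90 h minus 78 h of floxed and Sf1Cre ovaries the real groups were also on different slides. There the splits cannot tell the group from the slide. The number of calls for 90 h minus 78 h in floxed pituitary could be chance by the same measure, as 2 of 35 splits gave 3 or more and the highest other gave 767. This concerns the number of calls alone: Dbp rose by 2.90 in floxed and by 2.81 in the separate arrays of Sf1Cre glands, and Tef by 1.59 and 1.64. A count of 0 in limma is reached by every split, so the splits decide nothing for the Sf1Cre interaction (100 of 100, highest other 528), pituitary at 90 h (35 of 35 and 299) and the pituitary interaction (100 of 100 and 154). For Sf1Cre against floxed ovaries at 78 h, 3 numbers in the titles occur in both groups, and whether they pair the arrays is open. The 8 splits that part all 3 possible pairs were too few for a share under 0.05 (86 calls, highest other 0). The 27 splits that part fewer pairs gave up to 53, so that 1 of all 35 gave as many. Splits were also too few, at 10, for null 90 h minus 78 h (1966, highest other 1; 1 of 10 gave as many), for Sf1Cre pituitary 90 h minus 78 h (4 and 0; 1 of 10), for pituitary at 78 h (0 and 1; 10 of 10), for WT 90 h minus 78 h (0 and 0; 10 of 10) and for WT 90 h minus 66 h (0 and 5303; 10 of 10). Splits that called many more than the real one, as for WT 90 h minus 66 h, the Sf1Cre interaction, pituitary at 90 h, its interaction and its floxed 90 h minus 78 h difference, point to a structure of the samples other than the groups.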
